A study of Mus musculus with 8 samples.

How the data were processed

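miRNA abundance was measured in mouse footpad skin on 8 single-colour Agilent mouse miRNA arrays, 2 for each of 4 groups: wild-type and Dicer conditional knockout (cKO) embryos at embryonic day 16.5 (E16.5) and at E17.5. Per the labels, each replicate was a pool of footpad skin from 3 to 5 embryos, and the RNA was extracted as total RNA with the small RNA retained, labelled with Cy3 and hybridised to the array. Except for values raised to the floor described below, a p-value here measures the spread between such pools and not the spread between single embryos. The number of arrays limits the precision of every value. The array's probes are for mature miRNAs, so Dicer mRNA was not measured and the extent of the deletion is unknown. Whether unprocessed precursor hairpins add to the signal of a probe was not tested.

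The authors scanned the arrays and extracted the images with Agilent Feature Extraction 11.5.1.1. The deposited scanner files hold, for each of 56430 spots with a mouse miRNA probe per array, the background-subtracted fluorescence intensity in arbitrary linear units, per the file headers, with a mark for spots well above background. No scaling between arrays had been applied to it. The deposited value table holds a number for every probe on each array that equalled the scanner's signal within 0.02 in 100% of spots with a signal above 0. Between 42.2% and 45.1% of non-control spots per array had a signal of 0 or less. For these the table holds a constant of its array, which is also the table's median. At E16.5 it was 2.90 and 5.12 in the cKO arrays and 3.25 and 4.69 in the wild-type arrays. At E17.5 it was 3.07 and 3.75 in cKO and 3.37 and 3.60 in wild type. The table is thus on the linear scale, uncentred and unscaled between arrays. Among signals above 0, higher numbers stand for more miRNA. A signal above 0 but below the constant ranks under signals of 0 or less there. The main values were computed from the scanner files, and the table served as an alternative.

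The 4 groups fill 4 columns of a single slide, and replicate number goes with the slide row (replicate 1 in row 2, replicate 2 in row 1). There is no second slide or batch to compare, and the position of a group on the slide and the group itself cannot be told apart. No spot was saturated (0 spots). Between 2.84% and 6.02% of spots per array carried an outlier mark and were left out.

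Spots of a probe were averaged on the linear scale. Each array was then divided by the 75th percentile of the 474 probes detected on all 8 arrays. A probe counted as detected on an array when more than 50% of its spots were well above background. Scaled values below a floor were raised to the floor, which was the median over arrays of the 5th percentile of detected probes (−4.24 on the log2 scale), and log2 was taken. Each of 1881 mouse miRNAs (4415 probes) was represented by its probe with the highest mean over the 8 arrays. The 385 miRNAs detected on both arrays of at least 1 group were tested, of which 261 were detected on all 8 arrays.

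A model with 4 group means was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a trend), and p-values were adjusted by the Benjamini-Hochberg method within each of 6 contrasts at 0.05. The residual degrees of freedom were 4 and the prior degrees of freedom 1.08. The contrasts were cKO minus wild type averaged over both stages, at E16.5 and at E17.5, the difference of these effects between stages, and E17.5 minus E16.5 in each genotype. Other packages were data.table (version 1.17.8), jsonlite 2.0.0, and matplotlib 3.10.9 in Python 3.11.15. Array-level totals were compared by two-sided exact permutation tests of 4 against 4 arrays, over 70 arrangements (smallest possible p = 0.0286) and, within stage, over 36 (smallest possible p = 0.0556). Where a miRNA was not well above background on both arrays of a group and was detected in the other group, its fold change is given as a bound ("at least"). The same was done for a named miRNA detected on 1 of 2 arrays of a group when both lay near the floor. The bound sets the dim group on each array at the lowest signal among probes well above background there, or at the miRNA's own signal if that is higher, whereas the fit uses the common floor, so a bound can exceed the fitted change. Where all arrays of a group lay at the floor, their spread was 0 by construction. The p-value of such a miRNA then understates the spread between pools.

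The model, the tests, the scaling, the alternatives, 12 miRNA lists and the rule for naming miRNAs were fixed before the data were examined. The lists were skin epithelium, keratinocyte differentiation and barrier, the miR-17 family of clusters, let-7, the imprinted chromosome 12 cluster expressed in mesenchyme, dermal mesenchyme and fibroblast, skeletal muscle, cartilage, endothelium, blood and immune cells, nerve and glia, and miR-451a as a miRNA made without Dicer. A further pair of lists took miRNAs by their miRBase number, 1000 or above against below 1000. Together they hold all tested miRNAs, so camera's result for either list fixes the opposite result for the other. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The naming rule took, for the effect averaged over both stages, the 12 largest passing decreases and increases with the same sign at both stages, every tested member of the skin epithelium list, miR-451a, and up to 4 members of any other list with the largest absolute fold. It took the 5 largest passing changes in each direction for a single stage and the 6 largest for the difference between stages and for each stage contrast.

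Probe coordinates are those the scanner files give on mm9, and 186 of the 385 tested miRNAs have one. The gene name table supplied with the data is for another assembly (GRCm38), so it gave names of host and neighbouring genes within 10 kb only and no coordinates. It gave 88 gene entries for the named miRNAs, some of which have several gene copies. No entry was found for miR-146a-5p or miR-486a-5p.

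The model fit was tested on simulated data made by adding changes to 120 of 385 miRNAs in 20 runs. For the effect averaged over both stages it recovered 88.8% of changes of 0.3 log2, 98.8% of 0.5 log2 and 100% of 1 log2, and called 1.51% of unchanged miRNAs. At E16.5 the same shares were 76.3%, 94.7%, 99.8% and 1.60%. At E17.5 they were 77.3%, 93.8%, 99.8% and 1.85%. The changes were added to scaled log2 values, equally in both directions, with independent normal noise. The scaling, the floor and correlation between miRNAs were thus not tested, so these shares need not hold for the real data.

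The alternatives tried were scaling on all probes, no scaling, quantile and median scaling, a normexp background correction with an offset of 50, the scanner's summed signal per miRNA, the mean over all probes of a miRNA, the deposited table, other detection filters and floors, robust and array-weighted fits, the replicate number as a block, and leaving out each array in turn. Added after the data were seen were scaling on 19 positive control probes and leaving out the 2 arrays with the fewest detected miRNAs. These were the second E16.5 wild-type array (279) and the second E16.5 cKO array (281). Without them a lone array per genotype is left at E16.5, and the spread between pools comes from the E17.5 arrays alone. The spike-in scaling that had been planned was not run, since 0 of its 12 probe sequences were well above background.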

Results

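Probes for mature miRNAs were read in embryonic mouse footpad skin, the site at which eccrine sweat glands form. Wild-type embryos were compared with embryos with a conditional knockout (cKO) of Dicer, the endonuclease that cleaves precursor hairpins into mature miRNAs. Signal from precursor hairpins was not told apart from that of mature miRNAs. The labels do not say in which cells Dicer was deleted. Tissue was taken at E16.5 and E17.5, and each of the 4 groups had 2 arrays, each hybridised with RNA pooled from 3 to 5 embryos. At E16.5, 367 and 279 of 1881 mouse miRNAs were detected on the wild-type arrays and 365 and 281 on the cKO arrays. At E17.5 the numbers were 384 and 375 in wild type and 383 and 352 in cKO. Each array's 5 brightest miRNAs carried between 76.4% and 83.3% of its miRNA signal. Replicate arrays correlated across miRNAs, which are not independent of each other, at r = 0.997 to 0.999. The first principal component, with 70.5% of the variance, separated the genotypes, and the next, with 21.5%, separated the stages.

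The comparison of cKO with wild type over both stages addressed which footpad miRNAs differed in abundance with the knockout. As the deleted cells and the extent of the deletion are unknown, a miRNA that did not fall may still depend on Dicer. The largest losses were in miRNAs of the epithelium. miR-200c-3p, which restrains epithelial-to-mesenchymal transition, fell by 3.36 ± 0.109 on the log2 scale (SE, 4 arrays per genotype, adjusted p = 2.26e-05), or 10.3-fold. miR-203-3p, an epidermal miRNA that promotes exit of keratinocytes from the stem cell state, fell by 3.19 ± 0.117 (adjusted p = 3.42e-05), and miR-205-5p, abundant in basal keratinocytes, fell by 3.12 ± 0.0949 (adjusted p = 2.26e-05). With the main scaling increases were more numerous but small, and the only miRNA with a fitted increase of at least 2-fold was miR-342-3p. Under 3 of the 6 scalings increases were fewer than decreases.

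All 11 tested members of the skin epithelium list fell, and all 11 also fell when adjusted over the list alone. Besides miR-200c-3p, miR-203-3p and miR-205-5p, these were miR-203-5p, the other members of the miR-200 family and the miR-183 cluster. miR-141-3p changed by −3.16, miR-429-3p by −2.94, miR-200a-3p by −2.19 and miR-200b-3p by −1.77. miR-182-5p changed by −1.76 and miR-96-5p by −1.41 (adjusted p = 3.02e-04). miR-203-5p and miR-183-5p were not well above background on any cKO array, so that their falls are bounds: at least 4.38-fold for miR-203-5p and at least 3.07-fold for miR-183-5p. At E16.5 miR-200c-3p and miR-429-3p were detected on 1 of 2 cKO arrays. The median of the list was −2.19, with these bounds in place, and −2.35 relative to the median of all tested miRNAs. Camera gave adjusted p = 1.44e-15, and adjusted p = 0.258 with an estimated correlation; fry, which tests whether the members move one way, gave adjusted p = 2.43e-05. The list fell with all 11 members under each of 6 scalings of the arrays.

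**Figure D1:**
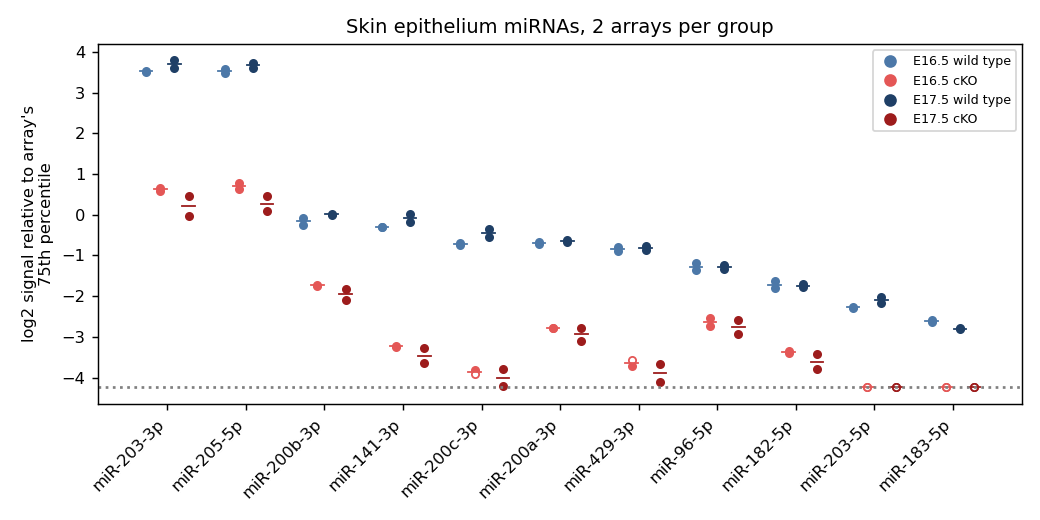
Log2 signal of the 11 tested skin epithelium miRNAs relative to the 75th percentile of each array, by group. Points are single arrays, dashes are means of 2 arrays, open points were not well above background, and the dotted line is the floor at −4.24. miR-203-3p lay at 3.52 and 3.70 in wild type at E16.5 and E17.5 and at 0.63 and 0.22 in cKO.

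These miRNAs come from few loci. On mm9 the probe of miR-200c-3p matched chromosome 6 from 124668392 to 124668406, beside miR-141-3p at 124667985 to 124668000. The miR-183 cluster is on the same chromosome, with miR-182-5p at 30115934 to 30115948, miR-96-5p at 30119471 to 30119491 and miR-183-5p at 30119677 to 30119694, within the host transcript Mirc35hg. The remaining miR-200 members are on chromosome 4 within Gm13648, with miR-429-3p at 155428068 to 155428085, miR-200a-3p at 155429063 to 155429079 and miR-200b-3p at 155429840 to 155429855. miR-203-3p matched chromosome 12 from 113369143 to 113369159, and miR-203-5p from the other arm of its hairpin 113369102 to 113369121. miR-205-5p matched chromosome 1 from 195333670 to 195333684, within its host transcript Mir205hg.

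Of 9 tested miRNAs of keratinocyte differentiation and barrier, 6 fell, 1 rose and 2 did not pass, with the same counts when adjusted over the list alone. Among them were miR-31-5p, which promotes keratinocyte proliferation (at least 3.57-fold lower, adjusted p = 5.15e-05; chromosome 4, 88556494 to 88556509), and miR-34a-5p, a p53 target (−1.72 ± 0.0525, adjusted p = 2.26e-05; chromosome 4, 149442585 to 149442603). miR-31-5p was detected on neither E16.5 cKO array, where its fall was at least 2.66-fold, and on 1 of 2 E17.5 cKO arrays, with both near the floor. miR-203-3p is in this list as well, miR-21a-5p changed by −0.26, miR-24-3p by −0.24 and miR-27b-3p by −0.14. The member that rose with the main scaling was miR-125b-5p, which restrains differentiation of skin stem cells (0.30). It was at −0.00933 without scaling and at −0.094 with control-probe scaling, and passed under neither. The list's camera test gave adjusted p = 2.91e-04, and adjusted p = 0.258 with an estimated correlation.

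The miR-17 cluster and its paralogs, which promote proliferation, fell in 8 of 10 members, and in 8 when adjusted over the list alone. miR-93-5p changed by −0.64 ± 0.0444 (adjusted p = 2.78e-04), miR-106b-5p, from the same host gene Mcm7, by −0.62, miR-20a-5p by −0.56 and miR-20b-5p by −0.55. The list median was −0.51, or −0.68 relative to all tested (camera adjusted p = 2.22e-08, and adjusted p = 0.258 with an estimated correlation). In the let-7 family, which restrains proliferation and accumulates with differentiation, 4 of 9 members fell over all miRNAs tested and 4 adjusted over the list alone. The members were miR-98-5p (−0.29), let-7d-5p (−0.28), let-7i-5p (−0.22) and let-7g-5p (−0.19), of which only let-7d-5p fell under all 6 scalings. The list had a camera adjusted p = 0.0112, adjusted p = 0.536 with an estimated correlation, and a fry adjusted p = 0.142. The median of the let-7 list was near 0 (0.0009) and its mean was −0.10. miR-221-3p, outside the naming rule and chosen after its values were seen, was the other miRNA that fell at least 2-fold as fitted (−1.21 ± 0.0349, adjusted p = 2.26e-05).

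Several miRNAs rose at both stages. The largest fitted increases of miRNAs detected in both genotypes were in miR-342-3p, from an intron of Evl and abundant in blood cells (1.04 ± 0.063, adjusted p = 1.89e-04), and miR-181a-1-3p, from a locus expressed in lymphoid cells (0.94 ± 0.0542, adjusted p = 1.53e-04; chromosome 1, 139863090 to 139863106), which was detected on 1 of 2 wild-type arrays at E16.5. miR-196b-3p, from the Hoxa cluster (chromosome 6, 52180138 to 52180151), was not well above background in wild type at either stage and rose at least 2.20-fold (adjusted p = 1.90e-04). These 3 were the only ones of the 176 increases that passed under all 6 scalings. The hairpin of miR-205 had arms of opposite sign: miR-205-3p (chromosome 1, 195333706 to 195333720) rose by 0.83 ± 0.121 (adjusted p = 0.00305), against −3.12 for miR-205-5p. The other named increases were miR-376c-3p at 0.73, miR-126a-5p at 0.55, miR-329-3p at 0.53, miR-379-3p at 0.51, miR-323-3p at 0.49, and miR-30e-3p, miR-135a-1-3p and miR-540-5p at 0.48 each. Of these, miR-323-3p and miR-135a-1-3p lay at the floor in wild type at E17.5, which limits their fitted changes.

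With the main scaling, in the imprinted cluster on chromosome 12, transcribed in mesenchyme, 27 of 30 members rose, as they did when adjusted over the list alone, among them miR-134-5p (0.47), miR-154-5p (0.45) and miR-411-5p (0.45). Its median was 0.31, or 0.15 relative to all tested (camera adjusted p = 2.91e-04, and adjusted p = 0.430 with an estimated correlation). In the dermal mesenchyme list, which shares miR-127-3p with that cluster, 8 of 10 members rose, 8 also adjusted over the list alone, including miR-199a-5p (0.41), miR-199a-3p (0.40), miR-214-5p (0.38) and miR-199b-5p (0.36), which mark fibroblasts. Relative to all tested this list had a median of 0.16 (camera adjusted p = 0.0456, and adjusted p = 0.258 with an estimated correlation), and its camera call was lost under each other scaling, with adjusted p from 0.0729 to 0.571.

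With the main scaling all 5 tested miRNAs of skeletal muscle rose, 5 also adjusted over the list alone, among them miR-499-5p (0.39), miR-1a-3p (0.36), miR-206-3p (0.32) and miR-133a-3p (0.29), which sustain myogenic differentiation (camera adjusted p = 0.0720). With control-probe scaling all 5 were below 0, and under 3 of the 6 scalings 0 of 5 passed as increases. Both miR-126a arms, made from the endothelial gene Egfl7, rose, 2 of 2 also adjusted over the list alone, and miR-126a-3p changed by 0.34. In blood and immune cells 4 of 7 rose, 4 also adjusted over the list alone: miR-146a-5p (0.37) and miR-223-3p (0.31), both of myeloid cells, miR-486a-5p of red cells (0.31) and miR-142a-3p, found in all blood cells (0.21). The other members included miR-144-3p at −0.22 (adjusted p = 0.306), and the list had a camera adjusted p of 0.512. miR-451a, a red cell miRNA matured by Ago2 without Dicer, was at 0.21 ± 0.157 (adjusted p = 0.301), so that a difference was not shown; without the first E16.5 wild-type array it was at 0.37 and passed. In nerve 2 of 3 rose, 2 also adjusted over the list alone, miR-128-3p (0.35) and miR-218-5p (0.21), while miR-219a-5p of oligodendrocytes was at 0.03 (camera adjusted p = 0.590). With the replicate number as a block 1 of these 3 rose. In cartilage 1 of 4 rose, miR-455-3p (0.38), which was also the only one adjusted over the list alone. miR-140-3p was at 0.17, miR-140-5p at 0.16 and miR-455-5p at 0.02 (camera adjusted p = 0.962). The sign of both miR-140 arms rested on 1 array: without the first E17.5 cKO array they were at −0.17 (3p) and −0.16 (5p).

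In all, 56 of 385 miRNAs fell and 176 rose, 14 and 1 of them at least 2-fold as fitted, and 168 of those that rose did so by less than 0.5 log2. The median change of all tested miRNAs was 0.17. The number of increases depended on the scaling: 75.9% of calls were increases in the main analysis (176 higher, 56 lower), 70.3% with quantile scaling (147 and 62), 67.2% with median scaling (129 and 63), 11.8% with scaling on all probes (6 and 45), 10% without scaling (6 and 54) and 4.57% with scaling on the positive control probes (8 and 167). Under all 6 scalings 42 miRNAs fell, among them all 11 of the skin epithelium list, miR-31-5p, miR-34a-5p, miR-93-5p and miR-106b-5p. With control-probe scaling the median change was −0.15 and no list of another cell type held an increase (0 members): the medians were −0.07 for dermal mesenchyme, −0.07 for muscle, −0.08 for blood, 0.05 for endothelium, −0.18 for nerve and −0.23 for cartilage, against −2.58 for skin epithelium. On that scale all 10 miR-17 and all 9 let-7 members fell, while 8 members of the chromosome 12 cluster fell and 0 rose.

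**Figure D2:**
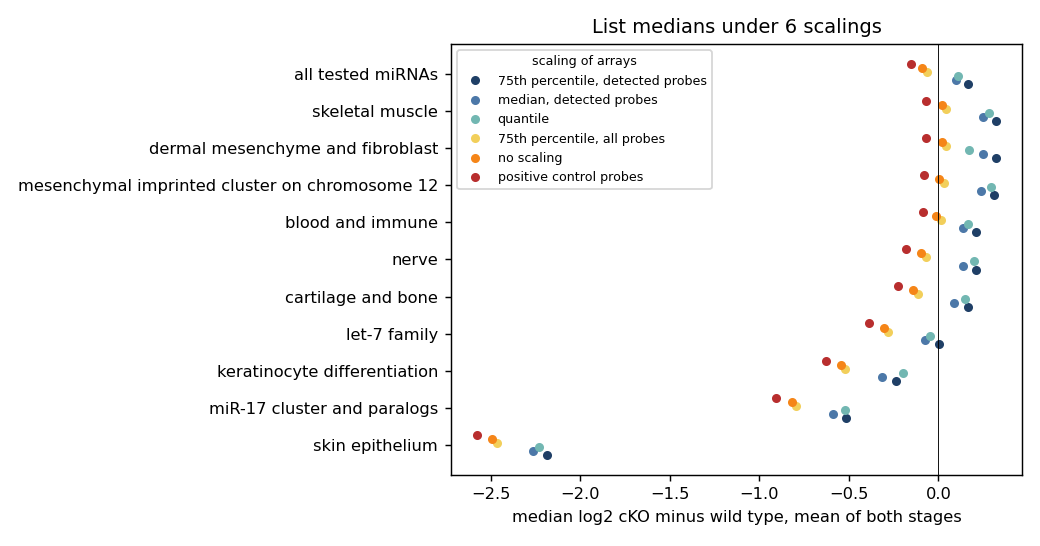
Median log2 difference, cKO minus wild type over both stages, of each miRNA list under 6 scalings of the arrays. Skin epithelium lies between −2.58 and −2.19 and miR-17 below 0 under every scaling, whereas the median of most other cell types is above 0 with the main scaling and below 0 with control-probe scaling.

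The size of the miRNA set did not differ detectably between genotypes. On average 345.25 miRNAs (SD 44.7, 4 arrays) were detected in cKO and 351.25 (SD 48.7) in wild type, with a two-sided exact permutation p of 0.714, or 0.778 with permutation within stage. The log2 median of the unscaled signal was 6.05 (SD 0.15) in cKO and 6.34 (SD 0.35) in wild type, a difference of −0.29 (exact permutation p = 0.171, within stage 0.167). Without the second E16.5 wild-type array this difference was larger and passed the exact permutation test over all arrangements. Wild type then rested mostly on E17.5 arrays (6.58 and 6.59, against 6.37 for the E16.5 array left). That difference thus mixes stage with genotype. The positive control probes differed by 0.08 (exact permutation p = 0.743). Measured relative to these probes, which was chosen after the data were seen, the median signal was lower by −0.38 in cKO (exact permutation p = 0.0286, within stage 0.0556), in each case the smallest p the design allows.

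At E16.5 the comparison asked which of these differences were present at the earlier stage. The epithelial miRNAs were already low: miR-200c-3p fell by 3.15 ± 0.154 (SE, 2 arrays per genotype, limma adjusted p = 1.56e-04), followed by miR-141-3p (−2.92), miR-203-3p (−2.90), miR-205-5p (−2.83) and miR-429-3p (−2.80). Of miRNAs detected in both genotypes miR-342-3p rose the most (1.34 ± 0.0892, limma adjusted p = 4.16e-04), then miR-181a-1-3p (0.97), miR-205-3p (0.85) and miR-376c-3p (0.85), and miR-196b-3p rose by at least 1.76-fold. All 11 skin epithelium members fell, 11 also adjusted over the list alone, with a median of −2.08 (camera adjusted p = 1.63e-13, and adjusted p = 0.190 with an estimated correlation). The miR-17 list fell in 8 of 10 members (camera adjusted p = 3.09e-07, and adjusted p = 0.190 with an estimated correlation) and let-7 in 4 of 9 (camera adjusted p = 0.00567, and adjusted p = 0.513 with an estimated correlation). The fry adjusted p was 9.48e-04 for miR-17 and 0.0923 for let-7. In the chromosome 12 cluster 18 members rose and 2 fell, or 21 and 2 adjusted over the list alone. In dermal mesenchyme 7 rose and 1 fell, or 8 and 1 adjusted over the list alone, the decrease being miR-143-3p of smooth muscle (−0.18). In muscle 4 of 5 rose, or 5 adjusted over the list alone, and in nerve 0 of 3 passed (1 with the replicate number as a block). The chromosome 12 cluster had a camera adjusted p = 0.0115, and adjusted p = 0.513 with an estimated correlation. The dermal mesenchyme (camera adjusted p = 0.216), muscle (camera adjusted p = 0.106) and nerve (camera adjusted p = 0.727) lists did not pass. The counts of the miR-17, let-7 and nerve lists were the same when adjusted over the list alone.

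Over all miRNAs, 138 rose and 58 fell at E16.5, and 1 and 17 did so under all 6 scalings. Increases made up 70.4% of calls in the main analysis, 64.4% with quantile, 66.3% with median, 21.7% with all-probe, 15% with no and 8.33% with control-probe scaling. The number of increases fell to 62 without the first E16.5 cKO array and to 47 in a fit of the E16.5 arrays alone.

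At E17.5 the epithelial miRNAs fell as well. miR-200c-3p fell by 3.56 ± 0.154 (SE, 2 arrays per genotype, limma adjusted p = 1.28e-04), miR-203-3p changed by −3.48, miR-205-5p by −3.40, miR-141-3p by −3.39 and miR-429-3p by −3.08. The named increases were miR-196b-3p, at least 2.75-fold, miR-181a-1-3p (0.92), miR-205-3p (0.82), miR-329-3p (0.79) and miR-342-3p (0.74). Again 11 of 11 skin epithelium members fell, 11 also adjusted over the list alone, with a median of −2.29 (camera adjusted p = 2.23e-16, and adjusted p = 0.220 with an estimated correlation). Of the miR-17 list 7 of 10 fell (camera adjusted p = 2.55e-07, and adjusted p = 0.220 with an estimated correlation). In let-7 1 of 9 fell, let-7d-5p at −0.19, and 0 adjusted over the list alone. The chromosome 12 cluster rose in 28 of 30 members (camera adjusted p = 1.31e-06, and adjusted p = 0.307 with an estimated correlation) and dermal mesenchyme in 9 of 10 (camera adjusted p = 0.00849, and adjusted p = 0.220 with an estimated correlation), while 5 of 5 muscle and 3 of 3 nerve miRNAs rose. The muscle (camera adjusted p = 0.0774), nerve (camera adjusted p = 0.263) and let-7 (camera adjusted p = 0.163) lists did not pass. All these counts except that of let-7 were the same when adjusted over the list alone. With the replicate number as a block, 1 of the 3 nerve miRNAs rose.

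In total 138 miRNAs rose and 39 fell at E17.5, of which 2 and 27 did so under all 6 scalings. Increases made up 78% of calls in the main analysis, 71.9% with quantile, 57.3% with median, 11.1% with all-probe, 8% with no and 1.55% with control-probe scaling. Without the second E17.5 wild-type array 81 increases passed.

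The effect at the 2 stages was compared to ask whether the difference between genotypes changed from E16.5 to E17.5. Of the decreases at E16.5 and E17.5, 37 were shared, against 5.88 if the calls were independent, and of the increases 88 were shared, against 49.5. The stages share 1 variance per miRNA and the same scaling, so their calls are not independent and these numbers are no test. The effects correlated across miRNAs at r = 0.88 (Spearman's rho 0.48), and miRNAs are not independent replicates. A difference between stages passed for 6 miRNAs. miR-6997-5p, from the gene Sptan1, had a difference of −2.02 ± 0.158 (adjusted p = 0.00594): it was at 0.28 at E16.5 (adjusted p = 0.0852) and fell by 1.74 at E17.5 (adjusted p = 3.34e-04). miR-298-5p differed by 0.40 (adjusted p = 0.0219; −0.45 at E16.5, −0.05 at E17.5) and miR-324-5p by 0.37 (adjusted p = 0.0491). miR-7212-3p (−0.59), miR-149-3p (−0.45) and miR-33-5p, from an intron of the sterol regulator Srebf2 (0.20), were near the floor. miR-7212-3p was not detected in either genotype at E17.5, and the difference of miR-33-5p was −0.16 with scaling on all probes. miR-143-3p and miR-431-5p, chosen after their values were seen, were the 2 with opposite calls: −0.18 and −0.20 at E16.5 against 0.21 and 0.16 at E17.5.

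None of the members of the skin epithelium list passed for a difference between stages (0 of 11, or 1 adjusted over the list alone, miR-183-5p, which was not well above background in cKO at either stage). The list as a whole, at −0.33 relative to all tested, passed only with camera at the preset correlation (camera adjusted p = 0.0157, and adjusted p = 0.699 with an estimated correlation). It did not pass with fry (adjusted p = 0.471). With 3 members passing adjusted over the list alone and 0 over all miRNAs, the dermal mesenchyme list differed by 0.12 (camera adjusted p = 0.0150, and adjusted p = 0.253 with an estimated correlation) and the chromosome 12 cluster, with 11 and 0, by 0.13 (camera adjusted p = 1.33e-04, and adjusted p = 0.472 with an estimated correlation). The fry adjusted p was 0.00797 for dermal mesenchyme and 0.0533 for the chromosome 12 cluster. For the nerve list, which differed by 0.29, the tests did not agree. Of its 3 members 2 passed adjusted over the list alone and 0 over all miRNAs, camera gave adjusted p = 0.0892 (0.0129 to 0.0892 over the 6 scalings) and fry gave adjusted p = 0.00797 (0.00458 to 0.973). The late-numbered miRNAs, those with a miRBase number of 1000 or above, differed by −0.27 (camera adjusted p = 2.79e-15, adjusted p = 0.399 with an estimated correlation, and fry adjusted p = 0.334). No miRNA passed under all 6 scalings (0). The number passing ranged over these scalings from 0 with scaling on all probes, where 27 had an unadjusted p under 0.05, to 21 with quantile scaling.

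**Figure D3:**
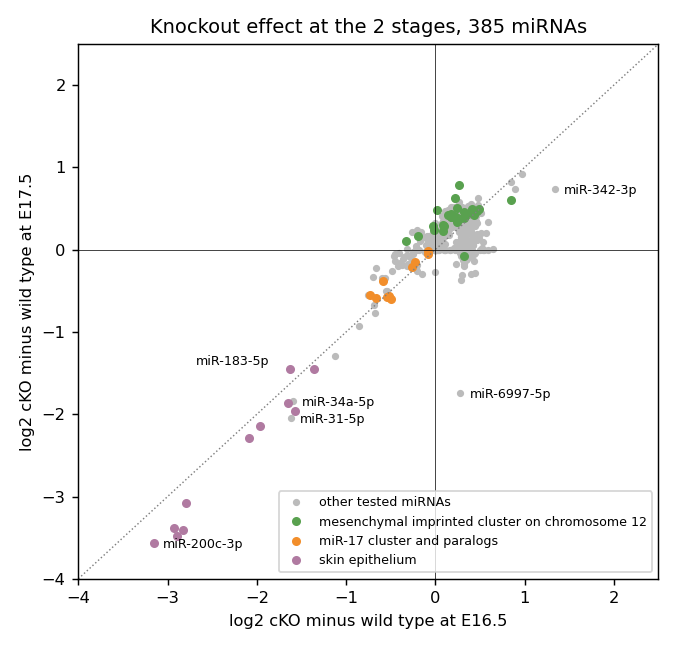
Log2 difference, cKO minus wild type, at E16.5 (horizontal axis) and E17.5 (vertical axis) for 385 miRNAs, each a difference of means of 2 arrays, with miRNA lists in colour and equal effects on the dotted line. The 11 skin epithelium miRNAs lie low at both stages and miR-6997-5p lies at 0.28 and −1.74.

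The change from E16.5 to E17.5 in wild type addressed normal development of the footpad. The clearest losses were of 3 dim miRNAs that were not well above background in wild type at E17.5: miR-3063-3p, from the gene Igf2bp1, fell at least 6.04-fold (limma adjusted p = 3.20e-04, 2 arrays per stage), miR-302c-3p, of an embryonic stem cell cluster in Larp7, at least 5.26-fold (limma adjusted p = 3.20e-04) and miR-7661-3p, from Itpr1, at least 4.48-fold (limma adjusted p = 8.45e-04). All 3 lay at the floor on both E17.5 wild-type arrays, so their p-values take no spread from that group. The largest gain was in miR-6997-5p (1.90 ± 0.112, adjusted p = 8.76e-04), followed by members of the miR-466 and miR-467 families, miR-466h-3p (0.72), miR-467f (0.67), miR-466q (0.66) and miR-466f-3p (0.59), and by miR-342-3p (0.53). Smaller named decreases were those of miR-433-3p (−0.66), miR-106b-3p (−0.55, and 0.055 without scaling) and miR-674-5p (−0.53, and 0.081 without scaling). miR-302c-3p matched chromosome 3 from 127248327 to 127248345 and miR-3063-3p chromosome 11 from 95824672 to 95824685, while the probes of miR-6997-5p and miR-7661-3p have no coordinates in the files.

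Epithelial miRNAs changed little in wild type: of 11 only miR-183-5p passed (−0.18). In the chromosome 12 cluster 3 rose and 4 fell (4 and 5 adjusted over the list alone), in let-7 1 rose (0 adjusted over the list alone), and in the miR-17 list 2 fell (2 adjusted over the list alone). Among muscle miRNAs 0 of 5 passed over all miRNAs tested and 3 rose adjusted over the list alone (camera adjusted p = 0.00455, and adjusted p = 0.687 with an estimated correlation). Of 107 late-numbered miRNAs 1 rose and 10 fell, or 1 and 5 adjusted over the list alone (camera adjusted p = 0.00305, and adjusted p = 0.687 with an estimated correlation). Decreases over all miRNAs numbered 41 with the main, 21 with quantile, 11 with median, 9 with control-probe, 4 with all-probe and 4 with no scaling. The fry adjusted p was 0.200 for the muscle list and 0.200 for the late-numbered list. In total 16 miRNAs rose and 41 fell, and 8 passed without the second E17.5 wild-type array. Increases made up 28.1% of calls in the main analysis, 52.3% with quantile, 71.1% with median, 76.5% with all-probe, 91.2% with control-probe and 97.8% with no scaling, so that the balance of gains and losses turned with the scaling. Under all 6 scalings 8 rose, among them miR-6997-5p, miR-466h-3p, miR-467f, miR-466q and miR-466f-3p, and the 3 dim miRNAs fell; with a normexp background correction miR-466q was at −0.05 and miR-466f-3p at −0.11.

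**Figure D4:**
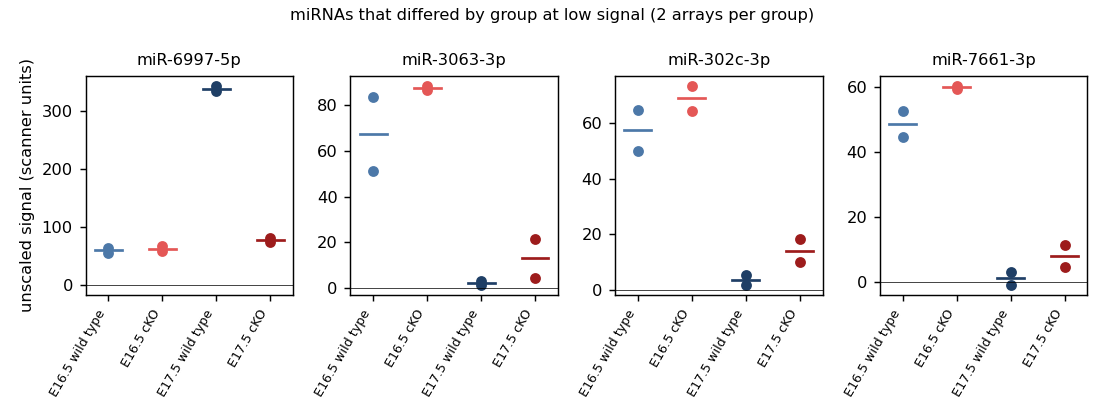
Unscaled background-subtracted signal of miR-6997-5p, miR-3063-3p, miR-302c-3p and miR-7661-3p on each array, by group; lines are means of 2 arrays. miR-6997-5p was at 344 and 335 on the E17.5 wild-type arrays and between 55.6 and 80.2 on the others, and miR-302c-3p was between 50.2 and 73.4 at E16.5 and between 1.93 and 18.2 at E17.5.

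The change with stage in cKO addressed whether the footpad miRNAs changed in the knockout as well. The same dim miRNAs fell: miR-3063-3p at least 6.33-fold (2 arrays per stage, limma adjusted p = 4.69e-05) and miR-302c-3p at least 5.44-fold (limma adjusted p = 6.48e-05), each detected on 1 of 2 E17.5 arrays and near the floor on both, and miR-7661-3p at least 5.27-fold. Also lower were miR-7212-3p, at least 2.5-fold, miR-8105 (−0.88) and miR-30b-3p (−0.76). The named increases were miR-136-5p (0.44), miR-466f-3p (0.42), miR-195a-5p, which restrains the cell cycle (0.39), miR-376b-5p (0.39), miR-29a-3p, a repressor of collagen synthesis (0.37), and miR-101a-3p (0.37). No member of the skin epithelium list passed (0 of 11, median −0.22, camera adjusted p = 0.184).

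The chromosome 12 cluster rose in 12 of 30 members and fell in 1, or in 14 and 1 adjusted over the list alone (camera adjusted p = 1.36e-04, and adjusted p = 0.488 with an estimated correlation). In let-7 3 of 9 rose (camera adjusted p = 0.00517, and adjusted p = 0.488 with an estimated correlation) and in muscle 3 of 5 (camera adjusted p = 0.0163, and adjusted p = 0.488 with an estimated correlation), with the same counts adjusted over the list alone. The late-numbered miRNAs fell in 58 of 107 members and rose in 1, or 66 and 1 adjusted over the list alone, with a median of −0.41 (camera adjusted p = 8.11e-22, and adjusted p = 0.462 with an estimated correlation). Decreases over all miRNAs numbered 78 with the main, 60 with quantile, 78 with median and 65 with control-probe scaling. Only 5 passed with all-probe and 5 with no scaling, so at most 5 of the 58 late-numbered decreases were kept under either. The fry adjusted p was 0.0280 for each of the chromosome 12, muscle and late-numbered lists and 0.0598 for let-7. In total 58 miRNAs rose and 78 fell, and 32 passed without the first E17.5 cKO array. Increases made up 42.6% of calls in the main analysis, 62.0% with quantile, 34.5% with median, 28.6% with all-probe, 32.3% with control-probe and 82.1% with no scaling. Under all 6 scalings miR-29a-3p rose and miR-3063-3p, miR-302c-3p, miR-7661-3p and miR-30b-3p fell, and with the normexp correction miR-29a-3p was at −0.16, miR-466f-3p at −0.090 and miR-101a-3p at −0.067, with miR-195a-5p and miR-376b-5p near 0. The changes with stage correlated between genotypes across miRNAs at r = 0.65 (rho 0.59), with 16 miRNAs falling in both against 8.31 if independent, and 10 rising in both against 2.41. Calls in the genotypes share 1 variance per miRNA and the same scaling, so they are not independent and these numbers are no test.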

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

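Apart from the counts over other splits of the arrays, every test used here to weigh an explanation was chosen after the result it bears on had been seen.

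Of the 35 splits of the 8 arrays into 4 and 4, only the real one gave as many decreases (56, against 7 in the highest other split). The same held for increases (176, against 7), 1 split in each case, under the main scaling. A genotype difference enters the residual of every other split and lowers its count, so this comparison does not exclude chance. Among the 35, the 18 splits with 2 arrays of each stage in both parts (highest other 3) are by themselves too few for a share under 0.05.

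The first pattern is that 176 miRNAs rose and 56 fell in the knockout of an enzyme that makes miRNAs. A technical explanation is the percentile scaling, which sets each array by miRNAs that themselves depend on Dicer: with scaling on the positive control probes 8 increases passed. That scale lowers the median change from 0.17 to −0.15, and 168 of the 176 increases were under 0.5 log2, so the lower count follows from a common shift and does not show which reference is right. A biological one is that less RNA from the deleted cells raised every other cell type's miRNAs alike. On the control-probe scale the medians of the 6 lists of other cell types spanned 0.28. That range was not larger than relabelling of their members gave (permutation p = 0.168). A common shift leaves the range unchanged, so it cannot show a rise, and on that scale all medians but that of endothelium (0.05) were below 0. An equal rise is left open and not shown, as what the positive control probes detect is not stated in the files.

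The second pattern is miR-6997-5p, flagged because the knockout effect differed between the stages by −2.02: it was bright on the E17.5 wild-type arrays (344 and 335) and nowhere else (55.6 to 80.2). A fault of single spots or of 1 probe can be set aside, since the smallest log2 difference over its 3 probes was 1.68. Each group fills 1 slide column, and the bright corner control was lower by −3.38 on the same arrays, so an effect of slide position may also be involved and cannot be separated from a biological change. The chosen probe is short, TCTGCACCTCTCCA. A true increase in wild type at E17.5 that is absent from cKO is the biological reading, and no second slide tests it.

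The third pattern is the loss of miR-3063-3p, miR-302c-3p and miR-7661-3p at E17.5 in both genotypes. A common target through a run of bases shared by all 3 probes can be set aside, because the longest such run was 2. Runs shared by only a pair of the probes were not counted. Carry-over of the bright corner control could lower them with that control, but their median log2 ratio to it changed by −1.73 (SE 0.258) or more between E16.5 wild type and E17.5 cKO, with undetected signals at their upper bound, where a constant ratio was predicted; this test replaced earlier ones after their values were seen. Slide position stays open, since stage goes with column. The 3 also differed by 0.53 between the columns of E16.5 cKO and wild type, but there column goes with genotype, so that difference does not bear on position. The biological explanation, loss with developmental stage, is not separable from slide position in this design.

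Of the other miRNAs flagged for a knockout effect that differed between the stages by a test of the difference, miR-7212-3p had −0.59, miR-149-3p −0.45, miR-298-5p 0.40, miR-324-5p 0.37 and miR-33-5p 0.20. Of these, miR-7212-3p, miR-149-3p and miR-33-5p were near the floor. miR-7212-3p was not detected in either genotype at E17.5, and the sign of miR-33-5p turned with the scaling.

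Lists were flagged for the same reason, relative to all tested miRNAs, with −0.33 for skin epithelium (camera adjusted p = 0.0157, and adjusted p = 0.699 with an estimated correlation) and 0.12 for dermal mesenchyme (camera adjusted p = 0.0150, and adjusted p = 0.253 with an estimated correlation). The chromosome 12 cluster had 0.13 (camera adjusted p = 1.33e-04, and adjusted p = 0.472 with an estimated correlation). miRNAs numbered 1000 or above had −0.27 (camera adjusted p = 2.79e-15, and adjusted p = 0.399 with an estimated correlation) and those below 1000 had 0.048 (camera adjusted p = 2.79e-15, and adjusted p = 0.122 with an estimated correlation). As these lists by number together hold all tested miRNAs, their camera results at the preset correlation are not separate findings. Fry gave adjusted p = 0.471 for skin epithelium, 0.00797 for dermal mesenchyme and 0.0533 for the chromosome 12 cluster. For the lists by number fry gave adjusted p = 0.334 (1000 or above) and 0.0533 (below 1000).

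Control probes outside the main measurement were flagged because their signal differed between genotypes: the positive control probes by 0.11 log2 at E17.5, and the bright corner probes, which mark the edge of the array, by 0.79 at E16.5 and 3.11 at E17.5 (cKO minus wild type).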

How the results depend on the processing

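Scaling on positive control probes and leaving out the 2 arrays with the fewest detected miRNAs were chosen after the data were seen. Both of these arrays are of E16.5, so a lone array per genotype is left at that stage and counts from that fit take no spread from it. The fall of the skin epithelium miRNAs, miR-31-5p, miR-34a-5p and the named miR-17 members over both stages kept its direction and its call under every alternative in which it was tested, whereas the number of increases and of stage changes did not; signal close to background limits miRNAs near the floor. Of these miRNAs, miR-203-5p, miR-183-5p, miR-200c-3p, miR-429-3p and miR-31-5p were not tested when only miRNAs detected on all 8 arrays were used. Over the planned and added alternatives, apart from leaving out single arrays, named miRNAs kept direction and call in 1516 comparisons. They were weaker in 222, stronger in 2 and reversed in 64. Lists, counted for the effect over both stages alone, kept their call in 62, were weaker in 18, stronger in 4 and reversed in 0. With single arrays left out, named miRNAs kept direction and call in 751 comparisons, were weaker in 90, stronger in 3 and reversed in 4. Lists then kept their call in 92 and were weaker in 4. A named miRNA counted as reversed on any change of sign. A list did so only if it passed in both settings in opposite directions, and never with fry. The numbers of reversals are thus not comparable. Except where a smaller set of miRNAs or arrays is part of the alternative itself, the cause was not tested. The planned spike-in scaling was not run, because 0 of the 12 spike-in probes were well above background.

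For the effect over both stages, the 56 decreases became 167 with control-probe scaling. The 176 increases became 6 with scaling on all probes, 6 without scaling, 14 with the deposited table and 8 with control-probe scaling. At E16.5 the 58 decreases became 18 with scaling on all probes, 17 without scaling and 99 with control probes. The 138 increases there became 5, 3 and 9 under the same 3 settings, 6 with the deposited table, 66 with no detection filter and 47 with only the arrays compared. At E17.5 the 39 decreases became 190 with control probes. The 138 increases there became 4 with scaling on all probes, 4 without scaling, 71 with median scaling, 9 with the deposited table and 3 with control probes. Without the 2 arrays with the fewest detected miRNAs, the effect over both stages had 53 decreases and 190 increases, of which 51 and 145 were among the 56 and 176.

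The 6 miRNAs whose effect differed between stages became 0 with scaling on all probes (27 with an unadjusted p under 0.05), 2 without scaling, 21 with quantile and 3 with median scaling. They became 13 with normexp, 22 with the scanner's summed signal, 17 with the mean of all probes, 3 with the deposited table, 2 with no detection filter and 1 with only miRNAs detected on all 8 arrays. They became 1 with a floor lowered by 2 log2 units, 3 with a robust fit and 13 with array weights.

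The 57 stage changes in wild type became 17 with scaling on all probes, 184 without scaling, 102 with control probes, 160 with normexp and 26 with the summed signal. They became 237 with the deposited table, 11 with no detection filter, 5 with only the arrays compared and 15 without the 2 arrays. The 136 stage changes in cKO became 7 with scaling on all probes, 28 without scaling, 89 with the summed signal, 43 with no detection filter and 57 with only the arrays compared. The 33 list calls over the 6 contrasts became 0 with an estimated correlation, 21 without scaling and 57 with fry's mixed test. Both lists by miRBase number are counted in these calls, although their camera results are not separate. The difference in detected miRNAs, −6, became 3 with the scanner's own detection flag. The difference in unscaled median signal, −0.29, became −0.38 relative to the control probes (exact permutation p = 0.0286).

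Leaving out each array in turn, with a lone array assumed to vary like the other groups, gave 50 to 57 decreases and 133 to 180 increases over both stages. It gave 48 to 55 and 62 to 135 at E16.5, and 33 to 41 and 81 to 143 at E17.5. The difference between stages ranged from 4 to 42 miRNAs, the stage change from 8 to 61 in wild type and from 32 to 139 in cKO, the list calls from 31 to 37, the detected difference from −30.1 to 15.4 and the unscaled median from −0.46 to −0.21. Increases at E16.5 became 62 without the first cKO array, 87 without the first wild-type array of that stage and 90 without either E17.5 wild-type array, and increases at E17.5 became 81 without the second E17.5 wild-type array. The difference between stages became 18 and 42 without the first and second E16.5 cKO arrays, 15 without the second E16.5 wild-type array and 12 without the first E17.5 cKO array. Wild-type stage changes became 36 without either E16.5 cKO array, 22 without the second E16.5 wild-type array, 31 and 32 without the first and second E17.5 cKO arrays, and 19 and 8 without the first and second E17.5 wild-type arrays. Stage changes in cKO became 55 without the first E16.5 cKO array, 32 and 43 without the first and second E17.5 cKO arrays and 49 without either E17.5 wild-type array. The detected difference became 15.4 without the second E16.5 cKO array and 4.92 and 1.92 without the first and second E17.5 wild-type arrays. The unscaled median became −0.46 without the second E16.5 wild-type array, with an exact permutation p of 0.0286. That comparison mixes stage with genotype, as wild type then rested mostly on E17.5 arrays.

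Among named miRNAs over both stages, control-probe scaling reversed 19: miR-451a (−0.18), miR-214-5p (−0.012), miR-199b-5p (−0.027), miR-499-5p (−0.00125), miR-1a-3p (−0.035), miR-206-3p (−0.066), miR-133a-3p (−0.10), miR-146a-5p (−0.022), miR-486a-5p (−0.079), miR-223-3p (−0.085), miR-126a-3p (−0.054), miR-128-3p (−0.042), miR-218-5p (−0.18), miR-219a-5p (−0.36), miR-455-3p (−0.00906), miR-140-3p (−0.22), miR-140-5p (−0.23), miR-455-5p (−0.37) and miR-125b-5p (−0.094). Scaling on all probes reversed miR-451a (−0.070), miR-218-5p (−0.070), miR-219a-5p (−0.25), miR-140-3p (−0.11), miR-140-5p (−0.12) and miR-455-5p (−0.26). No scaling and the deposited table reversed miR-451a (−0.10), miR-133a-3p (−0.018), miR-223-3p (−0.000212), miR-218-5p (−0.10), miR-219a-5p (−0.27), miR-140-3p (−0.14), miR-140-5p (−0.15), miR-455-5p (−0.29) and miR-125b-5p (−0.00933). Quantile scaling reversed miR-219a-5p (−0.11) and miR-455-5p (−0.10), median scaling miR-219a-5p (−0.043) and miR-455-5p (−0.058), and leaving out the 2 arrays miR-455-5p (−0.013). Single arrays moved miR-219a-5p between −0.016 and 0.080, miR-140-3p between −0.17 and 0.51, miR-140-5p between −0.16 and 0.48 and miR-455-5p between −0.025 and 0.059. miR-451a passed without the first E16.5 wild-type array (0.37), miR-219a-5p without the second (0.080) and miR-140-5p without the second E17.5 cKO array (0.48). The dermal mesenchyme call was lost without the second E16.5 cKO array (0.13 relative to all tested), the first or second E17.5 cKO array (0.15 and 0.17) or the first E17.5 wild-type array (0.15).

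The stage difference of miR-33-5p reversed with scaling on all probes (−0.16), no scaling (−0.28), quantile scaling (−0.00131), normexp (−0.033) and control probes (−0.088). In wild type without scaling or with the deposited table, miR-106b-3p was at 0.055 and miR-674-5p at 0.081, and with normexp miR-466q was at −0.052 and miR-466f-3p at −0.11. In cKO normexp reversed miR-466f-3p (−0.090), miR-195a-5p (−0.011), miR-376b-5p (−0.00607), miR-29a-3p (−0.16) and miR-101a-3p (−0.067).

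With the replicate number as a block, 56 decreases and 164 increases passed over both stages, 57 and 125 at E16.5, 37 and 132 at E17.5, 6 for the difference between stages, 47 and 122 for the stage changes in wild type and cKO, and 35 list calls. The 2 further list calls were increases of the muscle list over both stages and at E17.5. In the E17.5 comparison the nerve list had 1 increase with the block against 3, and let-7 had 0 decreases against 1. The nerve list had 1 increase against 0 at E16.5 and 1 against 2 over both stages, and counts of other lists moved as well. The differences between replicates of a pair of groups correlated across miRNAs at r = −0.14, 0.12, 0.24, 0.19, 0.15 and 0.28, of which 5 of 6 were above 0.1. As 1 of them was not, a pairing by number was not assumed, and the results were left without the block. The number also goes with the slide row, and the second array, in row 1, had fewer detected miRNAs than the first in all 4 groups.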

Other observations

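The groups of this part were chosen after their values had been seen, except for the lists by miRBase number.

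Both arms of a hairpin were tested for 49 miRNAs. With the main scaling both arms of 21 rose in the knockout over both stages, against 16 with quantile or median scaling and 0 with each of the other 3. Both arms fell for miR-203 and miR-31 under all 6 scalings; miR-31-5p fell at least 3.57-fold and miR-31-3p changed by −0.14. With the main scaling the arms of 3 hairpins passed in opposite directions. miR-205 had −3.12 for the 5p arm and 0.83 for the 3p arm, miR-1839 had −0.23 for 5p and 0.36 for 3p, and miR-652 had 0.34 for 5p and −0.09 for 3p. With control-probe scaling miR-205-3p was at 0.44 and passed, and miR-1839-3p (−0.033) and miR-652-5p (−0.050) did not. The arms of miR-205 passed in opposite directions under each scaling but that on all probes.

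The families miR-297, miR-466, miR-467 and miR-669, whose sequences are rich in repeats, had 15 tested members. Of these 5 rose and 0 fell from E16.5 to E17.5 in wild type, with a median of 0.04, and 3 rose in cKO (1 to 6 over the 6 scalings). The number that rose in wild type was 7 with scaling on all probes, 11 without scaling, 6 with quantile scaling, 5 with median scaling, 10 with control-probe scaling, 0 with a normexp background correction and 0 without either E17.5 wild-type array. In the knockout over both stages 4 of 15 rose with the main scaling, 2 rose and 1 fell with quantile scaling, 1 rose with median scaling, 0 rose and 1 fell with scaling on all probes and without scaling, and 0 rose and 8 fell with control-probe scaling. Outside the naming rule, miR-221-3p (0.25), miR-31-3p (0.28) and miR-669p-3p (0.46) also rose with stage in wild type under all 6 scalings.

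Further decreases in the knockout over both stages, outside the naming rule, were those of miR-210-3p, which is induced by low oxygen (−0.90 ± 0.0580, adjusted p = 2.20e-04), miR-196a-5p of the Hox clusters (−0.72), and miR-193a-3p and miR-365-3p (−0.68 and −0.65). All of them were present at both stages, with −0.86 and −0.93 for miR-210-3p at E16.5 and E17.5.

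The median of 107 miRNAs numbered 1000 or above was 0.21 in the knockout over both stages, where 48 rose and 2 fell, miR-6997-5p and miR-1839-5p, or 41 and 2 adjusted over the list alone (camera adjusted p = 0.0112, and adjusted p = 0.692 with an estimated correlation). With control-probe scaling 1 of these rose and 20 fell. Of 278 miRNAs numbered below 1000, 128 rose and 54 fell, or 7 and 147 with control-probe scaling, with a median of 0.12 (adjusted p = 0.430 with an estimated correlation).

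The bright corner control had a signal of 438 and 685 on the E16.5 cKO arrays, 428 and 233 on the E16.5 wild-type arrays, 326 and 309 on the E17.5 cKO arrays and 35.2 and 38.1 on the E17.5 wild-type arrays.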
